A study of Mus musculus with 4 samples.

How the data were processed

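Chromatin-associated total RNA of a mouse pancreatic ductal adenocarcinoma cell line was sequenced in 4 libraries, 2 with guides against Paf1 and 2 with random guides. Per the labels' protocols, dCas9-KRAB was induced with doxycycline at 1 µg/mL, RNA was extracted with TRIzol, and libraries were made with a total RNA kit. The labels do not describe the chromatin fractionation or a spike-in, so only relative amounts could be compared. Per the submitters' processing notes, Trim Galore 0.6.4, STAR 2.7.7a and featureCounts 2.0.1 were used with GRCm38.p6 (mm10). The annotation release, the strand setting and the treatment of reads with several placements are not given in the sources used here. The deposited values are whole raw counts per gene, 1 column per library, and per the file headers each gene is a set of exons, so intronic reads, which are common in chromatin RNA, do not enter unless they lie in an annotated exon.

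The table held 56262 genes. By identifier without version, 55227 were matched to GENCODE M21 for names, biotypes and the GC content of the longest transcript, and 54907 of these had the same coordinates. Genes without a match held 0.474% of counts. The table has 775 genes on patch or alternate-strain sequences, and genes with copies there could lose reads. Totals ranged from 5997502 to 7497183 counts per library, and genes with few counts have wide errors. No sample column was left unmapped.

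Columns were assigned to samples by guide name, and groups follow the sample titles. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 17078. Counts were scaled by TMM (factors 1.08 and 1.05 in the knockdown, 0.938 and 0.940 in the control). Genes were tested with edgeR 4.0.16 in R 4.3.3 (robust quasi-likelihood, 1 factor for group, Benjamini-Hochberg adjusted p under 0.05), and the SE is the log2 fold divided by the square root of F. CPM values were computed from the deposited counts with the TMM-scaled library sizes. Percent shares were computed from the deposited counts over all genes of a library.

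The 37 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes PAF1 complex members, tested genes within 100 kb of Paf1, the 12 largest rises and 12 largest falls, and up to 4 members per list with the smallest p. The largest changes needed an adjusted p under 0.05, a mean of at least 5 CPM, both knockdown libraries on the same side of both controls, and no predicted, clone or pseudogene name. Malat1 and the genes named for their overlap were chosen after their values were seen. Lists with at least 5 tested members (33) were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation and with fry. No list was called with an estimated correlation, and the smallest adjusted p was 0.759. That version also missed a simulated shifted list (adjusted p = 0.317). Ratios with 1 to 3 control counts carry an exact 95% Poisson interval.

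The edgeR step was tested on simulated counts of 16620 genes with 50 genes at each fold. It recovered 48% at 1.5-fold, 70% at 2-fold, 68% at 0.5-fold and 100% at 4-fold, with 5 false calls. Alternatives were DESeq2 size factors, total counts, no filter, at least 50 counts in 2 libraries, DESeq2 1.42.0, limma voom, abundant classes removed, libraries thinned to equal depth, and each library left out in turn. With 1 library left in an arm, it was assumed to vary like the other arm.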

Results

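Chromatin-associated RNA was sequenced from a mouse pancreatic ductal adenocarcinoma cell line, the common epithelial cancer of the exocrine pancreas. PAF1 is a subunit of the PAF1 complex, which travels with RNA polymerase II during elongation. Its gene was silenced by CRISPR interference, in which a guide RNA directs catalytically dead Cas9 fused to the KRAB repressor domain to a promoter, here after induction with doxycycline at 1 µg/mL. There were 2 knockdown libraries, each with its own Paf1 guide, and 2 control libraries, each with its own random guide. The deposited gene counts summed to 5997502 and 7068290 in Paf1 knockdown libraries 1 and 2 and to 7497183 and 6218730 in control libraries 1 and 2. The sample labels describe a knockdown with random guides, whereas the series design text speaks of a knockout with Rosa26 as control, and the labels were followed. The labels do not describe the cultures. Each library carries its own guide and each guide has 1 library, so guide, culture and technical differences within a group cannot be told apart. The p-values rest only on the spread between these libraries, which mixes them. Libraries of 1 group differed beyond sampling noise, with a chi-square per gene of 2.89 between the knockdown libraries and 1.98 between the controls. Values below are means ± SD over n = 2 libraries in TMM-scaled counts relative to library size (CPM), and folds are knockdown over control with the standard error (SE) of the log2 fold.

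The first question was whether the target was lower in the libraries labelled as knockdown. Paf1 (ENSMUSG00000003437.14, chromosome 7, 28392951 to 28399388 on the forward strand, GRCm38, protein-coding) was at 28.0 ± 3.76 CPM in the knockdown and 53.5 ± 2.74 CPM in the control (SD, n = 2). The counts were 198 and 186 in the knockdown libraries and 388 and 300 in the controls, so both libraries of each group stood on the side their labels give. This was a 1.92-fold fall (log2 −0.94, SE 0.12, adjusted p = 5.64e-11, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of the other PAF1 complex members, Leo1 rose 2.42-fold (log2 1.28, SE 0.11), Wdr61 rose 2.02-fold (log2 1.01, SE 0.12) and Ctr9 rose 1.44-fold (log2 0.53, SE 0.09). Rtf1 rose 1.17-fold with an adjusted p of 0.0397 in edgeR's quasi-likelihood test, a call that ended with DESeq2 (adjusted p = 0.178), with no filter (0.145), after thinning (0.0541), and without knockdown library 1 (0.236), control library 1 (0.167) or control library 2 (0.150). Cdc73 was at 154 ± 10.2 CPM against 157 ± 20.6 CPM and did not pass the test. Over the 6 members, 4 rose and 1 fell, and the same counts were obtained adjusted over the list alone.

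**Figure D1:**
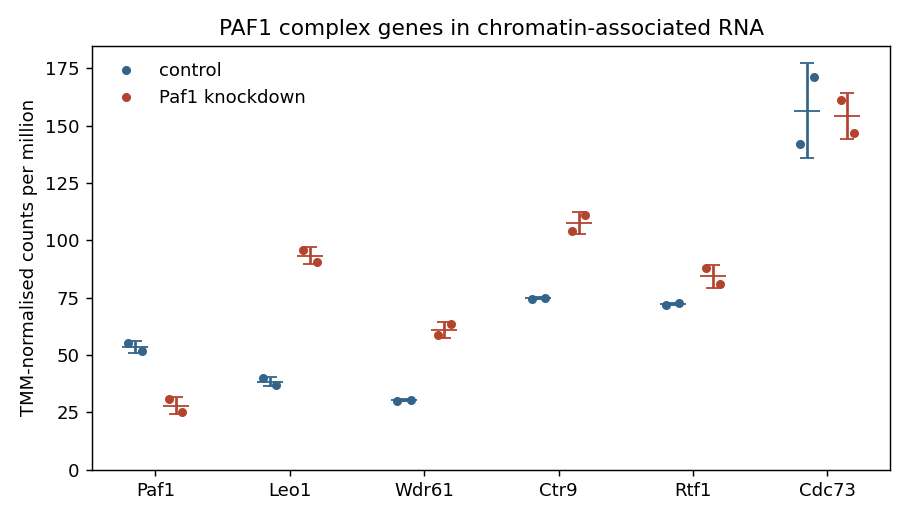
TMM-normalised CPM of the 6 PAF1 complex genes in each library (points), with the mean and SD of each group of 2 (bars). Paf1 lies at 28.0 CPM in the knockdown against 53.5 CPM in the control, while Leo1 lies at 93.3 CPM against 38.4 CPM.

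Because KRAB can silence chromatin around its target, the 9 tested genes within 100 kb of Paf1 were read in the same way. Supt5, which encodes the SPT5 subunit of the elongation factor DSIF, rose 1.53-fold (log2 0.61, SE 0.09). The others did not pass the test, among them the nearest genes on either side, Med29 at 5.32 ± 0.788 against 6.18 ± 2.17 CPM and Samd4b at 92.5 ± 0.185 against 91.8 ± 4.70 CPM. Rps16, Timm50, Zfp36, Plekhg2, Dll3 and the small RNA gene AF357399 had log2 folds of −0.07, 0.01, 0.21, −0.22, 0.07 and 0.18. The Med29 counts of 27 to 54 per library limit what could be detected there. Samd4b lies on the reverse strand and ends beside Paf1, while its 5' end at 28598144 lies outside the 100 kb. Its level therefore does not test silencing at a promoter near Paf1.

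The main comparison asked which genes differed between Paf1 knockdown and control. Many of the 12 largest rises were in genes that were nearly silent in the controls (under 1 CPM). The control means of Col11a2 (4.52), Zfr2 (3.49), Ccdc88b (1.92), Aqp2 (1.40) and Adm (1.23 CPM) were above that. Several of the genes are known from other tissues, a pattern that was not tested. By the second definition under Other observations, Tg, Eqtn, Tek, Cd248, Ankrd7 and Olfr691 lay within 50 kb downstream of an active gene on the same strand. Olfr461 had no active gene within 50 kb. Tg, the thyroglobulin gene, went from 0.558 ± 0.183 to 20.5 ± 1.85 CPM (36.2-fold, log2 SE 0.34). The sperm acrosome gene Eqtn went from 0.401 ± 0.162 to 14.1 ± 0.865 CPM, the endothelial receptor gene Tek from 0.558 ± 0.183 to 12.3 ± 0.115 CPM, and the olfactory receptor gene Olfr461 from 0.644 ± 0.304 to 17.5 ± 0.765 CPM. The largest falls included Prl2c2, a prolactin family gene also called proliferin, which fell 11.2-fold from 268 ± 31.3 to 23.7 ± 2.76 CPM (log2 −3.49, SE 0.10). Slc7a11, the cystine importer that feeds glutathione synthesis, fell 7.58-fold from 73.6 ± 2.10 to 9.75 ± 1.29 CPM, and the chemokine gene Ccl2 fell 7.52-fold from 34.4 ± 0.947 to 4.49 ± 1.54 CPM.

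In all, 5005 of 17078 tested genes rose and 4917 fell at an adjusted p under 0.05 in edgeR's quasi-likelihood test, and 1915 and 1488 of them changed at least 2-fold. Scaling by total gene counts without TMM shifted all folds up by 0.18 (log2) and made 65.0% of the called genes higher in place of 50.4%, so every direction here is relative to the bulk of genes. DESeq2 called 3299 higher and 3468 lower. The libraries of the groups did not overlap for 77.9% of tested genes, against 33.3% by chance. In simulated data of this design, edgeR recovered 70% of genes raised 2-fold and 48% of genes raised 1.5-fold. Only 50 of 16620 genes were changed at each fold there, whereas 58.1% of tested genes were called in the data. The adjustment was therefore stricter in the simulation, and its rates do not give the sensitivity of the calls above.

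Among the other 8 largest rises, the pericyte and tumour vessel gene Cd248 held 3 counts in the controls and 177 in the knockdown, a ratio of 54.7 with a 95% counting interval of 18.4 to 268. Ankrd7 rose by 4.90 (log2), Olfr691 rose 15.6-fold, Zfr2 8.43-fold, the kidney water channel gene Aqp2 8.39-fold, Ccdc88b 8.34-fold, the cartilage collagen gene Col11a2 8.04-fold and the adrenomedullin gene Adm 8.03-fold. Among the falls, the collagen genes Col23a1 and Col6a1 fell 11.2-fold and 6.53-fold, and the peroxisomal bile acid oxidase gene Acox2 fell 9.60-fold. Dnajb3 fell 6.21-fold, the kinase gene Stk39 5.95-fold, the retinol transporter gene Stra6 5.87-fold, Dus4l 5.82-fold, the aldehyde dehydrogenase gene Aldh3a1 5.76-fold and Frmpd1 5.53-fold. The strand setting of the counting is not given in the sources used here, so reads could not be told apart where genes overlap on opposite strands: Tg holds Sla (7.47 against 0.543 CPM), Adm overlaps Gm28863 (5.55 against 1.53 CPM), Stra6 overlaps Ccdc33 (1.08 against 2.09 CPM), Ccl2 overlaps Gm17268 (0.890 against 1.00 CPM), and Dnajb3 lies in the Ugt1a genes, of which Ugt1a7c was at 11.3 against 35.6 CPM. Prl2c2 and the olfactory receptor genes have close copies, and their values are uncertain to that extent.

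RNA from the mitochondrial genome was higher in the knockdown. Of 17 tested mitochondrially encoded genes, 15 rose and none fell, with the same counts adjusted over the list alone, and the median log2 fold was 1.13. The complex I subunit genes mt-Nd2 and mt-Nd1 both rose 2.34-fold (log2 1.23, SE 0.09), mt-Cytb of complex III rose 2.19-fold (log2 1.13, SE 0.09) and mt-Nd4 rose 2.15-fold (log2 1.10, SE 0.09). These genes took 1.25 ± 0.0407% of gene counts in the knockdown against 0.511 ± 0.00621% in the control (SD, n = 2), and 2 libraries against 2 cannot give a two-sided exact permutation p below 0.333. The list was called by camera with an adjusted p of 6.41e-05 (0.759 with an estimated correlation). The cytosolic ribosomal protein genes took 0.572 ± 0.00969% against 0.538 ± 0.00596% of counts, the replication-dependent histone genes 0.0610 ± 0.000134% against 0.0580 ± 0.000180%, and the nuclear-retained long noncoding RNA genes 3.48 ± 0.321% against 5.05 ± 0.00890%. Malat1, the most abundant of the last group and chosen after its values were seen, took 2.25% and 1.99% in the knockdown libraries and 3.14% and 3.16% in the controls.

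Cholesterol synthesis genes were lower. Of 25 tested members, 18 fell and 1 rose, the same counts adjusted over the list alone, with a median log2 fold of −0.72. The LDL receptor gene Ldlr fell 2.67-fold from 784 ± 17.3 to 294 ± 5.85 CPM (log2 −1.42, SE 0.09). Nsdhl fell 2.75-fold (log2 −1.46, SE 0.16), Lss, which encodes lanosterol synthase, 2.18-fold (log2 −1.12, SE 0.10) and Cyp51, the lanosterol demethylase gene, 2.17-fold (log2 −1.12, SE 0.09). The camera adjusted p was 6.41e-05 (adjusted p = 0.759 with an estimated correlation).

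Inflammatory target genes of NF-kB were also lower. Of 18 tested, 10 fell and none rose, 11 and none adjusted over the list alone, with a median log2 fold of −0.39. Besides Ccl2, the NF-kB subunit genes Nfkb2, Nfkb1 and Relb fell 1.86-fold, 1.75-fold and 1.91-fold. The camera adjusted p was 0.0359 (adjusted p = 0.759 with an estimated correlation). That camera call ended with total-count scaling (adjusted p = 0.0503), with at least 50 counts required (adjusted p = 0.0903), with abundant classes removed (adjusted p = 0.110), without knockdown library 1 (adjusted p = 0.127) and without control library 2 (adjusted p = 0.0803). No other list with at least 5 tested members was called, and 11 of the 33 such lists had an unadjusted camera p under 0.05. The directional test fry called 6 lists higher and 7 lower.

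Genes of homologous recombination and the replication stress response had 16 members that fell and 5 that rose of 31, the same adjusted over the list alone. Rad50, a subunit of the complex that binds broken DNA ends, fell 2.93-fold from 150 ± 7.67 to 51.3 ± 0.577 CPM, the checkpoint kinase gene Atr fell 2.51-fold and its activator gene Topbp1 2.56-fold. The list's camera adjusted p was 0.0501 (adjusted p = 0.759 with an estimated correlation). This camera adjusted p was under 0.05 with DESeq2 size factors (0.0498), no filter (0.00247), DESeq2 (0.0497) and voom (0.00390). It was above 0.05 with total counts (0.0505), at least 50 counts required (0.0903), abundant classes removed (0.088) and thinning (0.0544). With 1 library left out, the call depended on which library that was. The series title names R-loops, hybrids of RNA with template DNA. Of 29 R-loop resolution genes, 10 rose and 9 fell, the same adjusted over the list alone. In that list the Fanconi anaemia genes Fancd2 and Fanca fell 2.58-fold and 1.82-fold and Brca2 fell 2.05-fold, whereas Thoc1, of the mRNA export complex THO, rose 1.63-fold.

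Among transcription genes, 13 of 28 elongation factor genes rose and 7 fell. Polr2a and Polr2b, which encode the largest subunits of RNA polymerase II, rose 1.83-fold and 1.62-fold, and Ccnt1, the cyclin of P-TEFb, rose 1.52-fold. The nuclear exosome list had 10 genes that rose and 2 that fell of 21, with Exosc3 up 2.61-fold, Mphosph6 up 2.08-fold, Exosc5 up 1.69-fold and Zcchc7 down 1.56-fold. Integrator and 3' end processing genes were divided, 11 up and 8 down of 30, with Ints12 up 2.24-fold and Ints3 down 2.30-fold. Counts for these 3 lists were the same adjusted over the list alone.

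Of 25 p53 target genes 11 rose and 2 fell, the same adjusted over the list alone. The cyclin-dependent kinase inhibitor gene Cdkn1a rose 2.07-fold, Trp53inp1 2.97-fold and Btg2 2.48-fold, and Ephx1 fell 1.89-fold. Of 34 mitosis genes 17 fell and 4 rose, among them the cytokinesis gene Ect2 (2.43-fold lower) and the condensin gene Ncapg (1.92-fold lower). DNA replication genes were divided, with 13 up and 15 down of 40. There Slbp, the histone mRNA stem-loop binding protein gene, rose 2.10-fold and Pola1, the catalytic subunit gene of DNA polymerase alpha, fell 1.78-fold. Replication-dependent histone genes had 12 up and 17 down of 48, with Hist1h4i up 3.57-fold and Hist1h2bn down 2.87-fold, and near-identical copies make single histone genes uncertain. MYC target and ribosome biogenesis genes had 13 up and 8 down of 35. Of 82 cytosolic ribosomal protein genes 16 rose and 24 fell, 14 and 24 adjusted over the list alone, and their median log2 fold of −0.05 became 0.13 with total-count scaling. For the mitosis, replication, histone and MYC lists the counts were the same adjusted over the list alone.

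Signalling genes moved in both directions. Immediate early genes had 8 up and 7 down of 20, 8 and 9 adjusted over the list alone. The growth factor response genes Egr1, Fosb and Fos fell 4.63-fold, 4.05-fold and 2.54-fold, whereas Btg2, also a member of this list, rose 2.48-fold. Of 18 MAPK output genes 5 rose and 8 fell, with Myc up 2.19-fold from 117 ± 7.83 to 256 ± 7.49 CPM and the ETS factor gene Etv4 down 2.14-fold. Of 20 YAP/TEAD target genes 8 rose and 7 fell, with Amotl2 up 1.67-fold and Amotl1 down 2.27-fold. Of 20 interferon response genes 6 rose and 4 fell, 6 and 3 adjusted over the list alone, with Stat2 up 1.62-fold and Ifit2 down 2.69-fold. The MAPK and YAP/TEAD counts were the same adjusted over the list alone.

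Among stress responses, the integrated stress response list had 13 genes that fell and 6 that rose of 27, 14 and 6 adjusted over the list alone. Slc7a11 is a member, as is Aldh18a1 of proline synthesis, which fell 2.16-fold, while the lipoprotein receptor gene Vldlr rose from 0.415 ± 0.385 to 6.93 ± 0.396 CPM. Of 18 unfolded protein response genes 10 fell and 2 rose, with the transcription factor gene Xbp1 down 1.95-fold and the protein disulfide isomerase gene Pdia4 down 1.93-fold. Heat shock genes had 5 up and 3 down of 11, 6 and 4 adjusted over the list alone, with Dnaja1 up 1.83-fold. NRF2 target genes had 4 up and 8 down of 20, with the glutathione reductase gene Gsr down 1.81-fold. Hypoxia and glycolysis genes had 6 up and 10 down of 26, with Pdk1 down 3.86-fold and the hexokinase gene Hk2 down 1.77-fold. Autophagy and lysosome genes had 19 up and 6 down of 30, 20 and 7 adjusted over the list alone, with the autophagosome gene Map1lc3b up 2.55-fold and the cathepsin gene Ctsl up 2.17-fold. The unfolded protein, NRF2 and hypoxia counts were the same adjusted over the list alone.

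**Figure D2:**
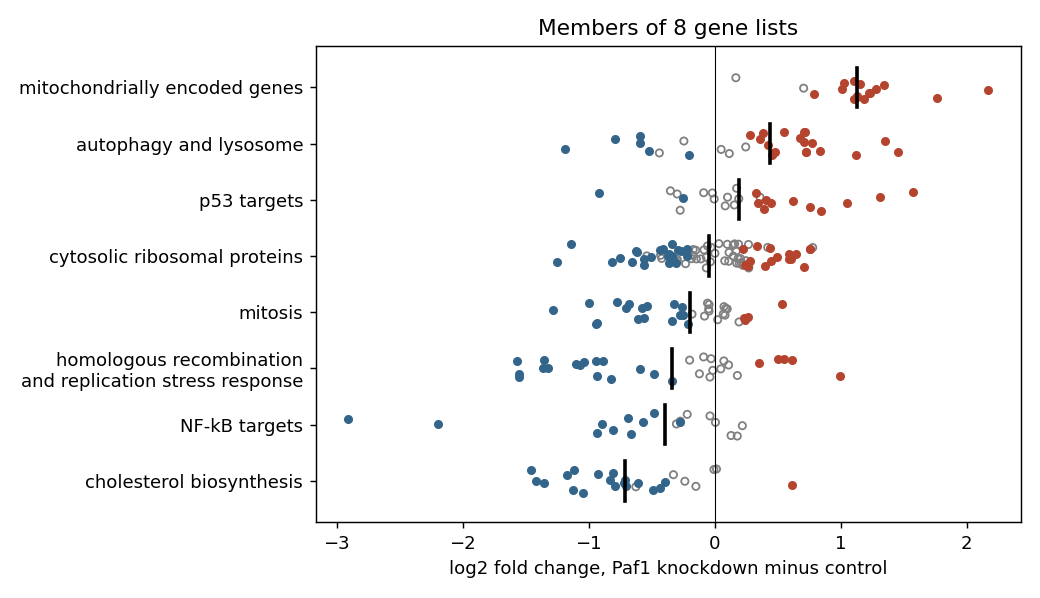
Log2 fold of each tested member of 8 gene lists, filled red where it rose, filled blue where it fell and open where it did not pass the test, with a black bar at the list median. The medians run from 1.13 for mitochondrially encoded genes to −0.72 for cholesterol biosynthesis, and total-count scaling turns the ribosomal protein median from −0.05 to 0.13.

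Cell identity genes were examined for epithelial and mesenchymal programmes and for other cell types. Of 16 epithelial genes 6 rose and 3 fell. The keratin genes Krt19 and Krt8 fell 1.94-fold and 1.75-fold, and the transcription factor genes Elf3 and Hnf1b rose 1.85-fold and 1.68-fold. Of 13 mesenchymal genes 9 fell and 2 rose, among them Fn1 (1.68-fold lower), Sparc (5.13-fold lower) and Vim (1.66-fold lower). The classical pancreatic cancer subtype list had 8 genes that fell and 2 that rose of 17, 8 and 3 adjusted over the list alone, with Hnf4a down 1.66-fold. The basal-like list had 3 that fell and 2 that rose of 11, with Hmga2 down 1.99-fold. The epithelial, mesenchymal and basal-like counts were the same adjusted over the list alone.

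Markers of other cell types were mostly below the test's filter. Tested were 4 of 11 endothelial, 3 of 20 acinar and 1 of 15 endocrine markers. Tek, Pecam1, Amy1 and Chgb passed the filter only through the knockdown libraries, so the counts of called markers are tilted towards rises. Below the filter, Cdh5 was at 0.495 CPM in the knockdown against 0.986 CPM in the control and Vwf at 0.377 against 0.901 CPM. Chga was at 0.677 against 0.758 CPM, while Cldn5 was at 1.84 against 0.572 CPM. Of 4 tested endothelial markers 3 were called higher, Tek, Flt1 (1.27-fold) and Pecam1, the last with 2 control counts and a ratio of 13.9 with a 95% counting interval of 3.53 to 120. Of 3 acinar markers 1 rose, the amylase gene Amy1 with a ratio of 37.1 and a 95% counting interval of 12.4 to 182, and 2 were called lower, Rbpjl and Bhlha15. The amylase genes Amy2a2 and Amy2a5, also on the acinar list, were at 0 CPM in both groups, so the rise of Amy1 does not stand for acinar genes as a set. The edgeR calls of Rbpjl, Bhlha15 and Flt1 ended with DESeq2 (adjusted p = 0.107, 0.172 and 0.152) and without knockdown library 2 (0.109, 0.104 and 0.217) or control library 1 (0.0861, 0.0509 and 0.189), and those of Cd79a and Cd14 ended with DESeq2 (0.0539 and 0.210). Further settings ended the call of Rbpjl (thinning, 0.0563), Flt1 (no filter, 0.0603), Bhlha15 (total counts 0.201, thinning 0.129, without knockdown library 1 0.0513, without control library 2 0.157) and Cd14 (total counts 0.112, without knockdown library 1 0.270, without control library 2 0.386). The 1 tested endocrine marker, Chgb, had a ratio of 13.5 with a 95% counting interval of 3.40 to 116. Of 6 fibroblast and stellate markers 3 fell and 1 rose, with Col3a1 down 3.89-fold from 331 ± 11.1 to 84.9 ± 5.72 CPM. Of 6 immune markers 1 rose, Cd79a, and 1 fell, Cd14, and adjusted over the list alone 1 rose and none fell. The counts of the other 4 marker lists were the same adjusted over the list alone. These intervals cover counting error only.

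Noncoding RNA was compared because chromatin holds nuclear transcripts. Of 14 nuclear-retained long noncoding RNA genes 6 fell and 2 rose. Neat1, the scaffold of paraspeckles, fell (log2 −0.97, SE 0.14), and the X-inactivation regulator gene Ftx fell 1.56-fold, while the imprinted antisense transcript Kcnq1ot1 rose 1.77-fold (log2 0.82, SE 0.11). Of 13 small nucleolar RNA host genes 5 fell and 1 rose, with Snhg6 down 2.13-fold, and of 4 abundant structural RNA genes 2 rose, with Scarna2 up 2.59-fold. The counts of these 3 lists were the same adjusted over the list alone. Over all 1980 long noncoding genes 579 rose and 425 fell, and their median log2 fold lay 0.13 above that of protein-coding genes, which did not pass camera (p = 0.204, and p = 0.609 with an estimated correlation). That difference was 0.0243 without knockdown library 1, 0.236 without control library 2 and 0.322 with no filter. By annotated class, which was not tested, 217 of 954 antisense genes rose and 238 fell, 204 of 521 lincRNA genes rose and 91 fell, 79 of 271 processed transcripts rose and 47 fell, 54 of 176 sense intronic genes rose and 48 fell, and 21 of 48 bidirectional promoter genes rose and 1 fell.

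Since PAF1 acts in elongation, folds were set against the genomic span of each gene. Protein-coding genes of the longest decile, 119 to 2271 kb, had a median log2 fold of −0.50, and 62.2% of them fell while 11.6% rose. In the 4th decile, 12.5 to 17.5 kb, the median was 0.21, with 41.9% higher and 18.3% lower, the highest of the deciles. The relation was not monotonic, since the shortest decile, with a median span of 3.05 kb, had a median of 0.03, with 24.0% higher and 19.3% lower. Spearman's rho across genes between fold and span was −0.14 over all tested genes and −0.23 over protein-coding genes. Over all genes it was −0.0644 with no filter and −0.255 with at least 50 counts required. It was −0.12 to −0.16 for each knockdown library against each control. Genes are not independent replicates, so no p-value was attached.

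**Figure D3:**
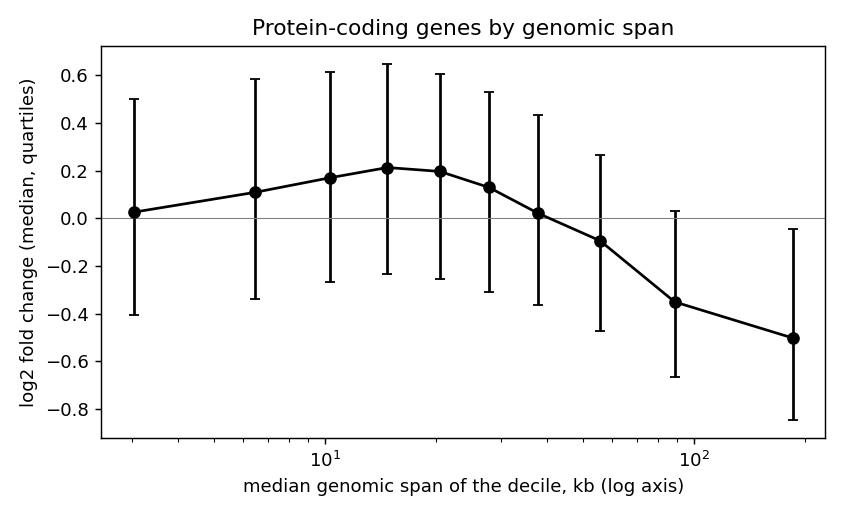
Median log2 fold of protein-coding genes, knockdown minus control, in 10 equal bins of genomic span on a log axis, with bars from the lower to the upper quartile of the genes in each bin. The medians go from 0.03 at a median span of 3.05 kb up to 0.21 at 14.8 kb and down to −0.50 at 185 kb.

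The replicates were different guides, so the guides were compared with each other. Across tested genes, Pearson's r between the change of guide 1 against 1 control and that of guide 2 against the other control was 0.837 and 0.840 for the 2 ways of assigning the controls. With the controls kept apart in the same way, the guides gave the same sign for 84.1% of tested genes.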

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

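All alternatives here were chosen before the data were examined. Paf1 stayed lower and past the threshold under each, with log2 folds from −0.76 to −1.08, and the counts of genes higher and lower moved by over 1.5 times only under DESeq2, with 3299 higher, and when at least a 2-fold change was required, with 1915 higher and 1488 lower. The cause of the differences below was not tested unless the setting itself shows it.

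The list counts of 1 higher and 2 lower moved most. Lists lower came to 1 with total counts, with at least 50 counts in 2 libraries and with abundant classes removed, and to 6 with no filter. Lists higher came to 0 with abundant classes removed, since that removes the mitochondrial genes. With voom there were 3 higher and 7 lower, with fry 6 and 7, and with an estimated correlation 0 and 0. Leaving out 1 library gave 1 to 2 lists higher and 1 to 6 lower. Rho against span was −0.0644 with no filter, −0.255 with at least 50 counts, −0.11 against exonic length, −0.23 for protein-coding genes, and −0.0949 to −0.142 with 1 library left out. Agreement between guides was 0.612 with no filter, 0.912 with at least 50 counts, 0.897 at a mean of at least 5 CPM, 0.828 with voom and 0.826 after thinning, and has no value with a library left out. The noncoding difference of 0.13 was 0.32 with no filter and 0.0243 to 0.236 with 1 library left out, the lowest without knockdown library 1. Of the other 165 genes tracked, 1903 of 1953 values kept their direction and side of the threshold, 30 lost and 3 gained the threshold, and 17 turned. Calls were lost for Rtf1, Bhlha15, Rbpjl, Flt1, Cd14, Cd79a, Lamb3 and Snhg15 and gained for Plekhg2 and Zfp36. All that turned were uncalled. With total counts these were Cdc73 (0.16) and Rps16 (0.11), with no filter Samd4b (−0.0239) and Timm50 (−0.0265), with at least 50 counts Cdc73 (0.0019), and after thinning Timm50 (−9.43e-05). With 1 library left out the ranges were −0.16 to 0.10 for Cdc73, −0.28 to 0.10 for Rps16, −0.0594 to 0.0549 for Samd4b, −0.11 to 0.11 for Timm50, −0.41 to 0.91 for Dll3 and −0.56 to 0.18 for Med29. Depth limits genes near 1 CPM.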

Other observations

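The tests in this part were all chosen after the results had been seen. Gene families were ranked by the shared start of their symbols, 119 families with at least 12 tested genes, and 9 groups were then drawn up from that ranking and from other classes, with p-values adjusted over all 127 sets, and the genes given as examples were chosen after their values were seen. The 119 include the symbols that begin with a digit, which share no start and did not enter the test. Of the families tested, camera called 7 higher and 3 lower. Of the 329 tested Zfp zinc finger genes, many of them DNA-binding repressors, 172 rose and 50 fell, with a median log2 fold of 0.48 (camera adjusted p = 9.25e-05). Examples are Zfp950 (log2 1.80, SE 0.10) and Zfp386 (log2 1.53, SE 0.09). Nuclear-encoded respiratory chain genes had 45 of 86 higher and 5 lower (median 0.45, camera adjusted p = 0.00138), with Ndufb5 at log2 1.57 (SE 0.12). Mitochondrial ribosomal protein genes had 32 of 74 higher and 4 lower (median 0.32, camera adjusted p = 0.0280), with Mrpl13 at log2 1.60 (SE 0.10). Of 44 tested olfactory and vomeronasal receptor genes, 25 rose and 5 fell (median 1.03, camera adjusted p = 0.00325). Receptor genes silent in the controls were tested only where the knockdown libraries lifted them past the filter, such as Olfr689 (8.41 against 0.0859 CPM). The filter thus tilts this median upwards, and it does not describe the untested receptor genes. Semaphorin genes had 8 of 16 lower and 1 higher (median −0.55, camera adjusted p = 0.0475), with Sema5a at log2 −2.10 (SE 0.11). No set was called with an estimated correlation, where these 5 all had an adjusted p of 0.851. Zinc finger and receptor genes have close copies, so reads shared between them leave single values uncertain.

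The remaining groups did not pass camera. Collagen and laminin genes had 20 of 33 lower and 8 higher (median −0.61, camera adjusted p = 0.0628), proteasome genes 15 of 34 higher and 3 lower (adjusted p = 0.256), solute carriers 62 of 222 higher and 68 lower (adjusted p = 0.681) and SNARE genes 17 of 36 higher and 8 lower (adjusted p = 0.466). The group called SNARE took all symbols that start with Vamp, Snap or Stx, so it also holds genes of other kinds, such as Snapc1. Against 10000 random lists matched on span and expression, the median of the cholesterol list lay at percentile 0 and those of the NF-kB, homologous recombination and mesenchymal lists at 0.18, 0.27 and 2.68. The Zfp, respiratory chain and receptor medians lay at percentile 100, and those of the mitochondrial ribosomal proteins, SNARE genes, proteasome, solute carriers, semaphorins and collagens with laminins at 99.3, 94.2, 85.9, 19.2, 2.60 and 0.16. Members of a list may vary together, which random lists do not copy, so these percentiles can be too extreme and are not tests. The estimated correlations were 0.101, 0.155, 0.128 and 0.0995 for the cholesterol, NF-kB, homologous recombination and mesenchymal lists. These all had negative medians, and no other fixed list was ranked in this way. Lists left out include the integrated stress response (median −0.46) and autophagy and lysosome (median 0.44). With total-count scaling the median of the solute carriers went from −0.02 to 0.16, and no other of the 9 groups changed sign.

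Many near-silent genes rose, and a candidate explanation for part of them is transcription running on from an active gene (at least 10 CPM) within 50 kb upstream on the same strand. Of 2 definitions tried, the first took genes under 1 CPM in the controls that reached 3 CPM and over 4 times the control level after 0.2 CPM was added (101 of 15959), and the second, written after the first had been seen, took genes that reached 4 CPM (73 of 16266) and also changed the biotypes taken, the rule for an active neighbour and the group compared against, so their odds ratios differ for several reasons. A rise was more frequent downstream of such a gene than where only the 5' end of an active gene faced the gene, 41 of 1574 against 19 of 1737 by the first (odds ratio 2.42, 95% interval 1.39 to 4.10) and 32 of 1522 against 13 of 2403 by the second (odds ratio 3.95, 95% interval 2.04 to 7.31), and by both definitions the interval excluded 1 for protein-coding genes (odds ratios 2.88 and 5.08) and genes of longer span (2.17 and 5.36) and included 1 for long noncoding genes (1.15 and 2.04) and genes of shorter span (3 and 2.21). These intervals treat genes as independent, which neighbouring genes may not be, and hold no spread between libraries. By the first definition 41 of 12648 genes (0.324%) without an active gene upstream in the window rose. By the second, 14 of 11210 (0.125%) without one on either side rose. Only protein-coding genes counted as active, and the first definition looked only upstream, so genes of each of its classes may have an active gene downstream. Run-on from noncoding or weaker genes, or from beyond 50 kb, was not looked at. For these genes both run-on and loss of repression stay open. By the second definition 14 of 1131 genes (1.24%) facing the 3' end of an active gene on the other strand rose. That decides nothing while the strand setting of the counting is not known. Neither group was tested against another. Chance at low counts is argued against by the mirror counts of 16 and 11 genes that went the other way. Of 62 near-silent fixed markers of other cell types, 2 reached 4 CPM, Amy1 and Tek. That is a larger share than the 0.449% of all near-silent genes by the second definition. The shares come from unlike sets, since genes overlapping an active gene were left out of the 0.449% but not of the markers. Amy1 is not among the 73 genes that rose there, and Tek lay downstream of an active gene on the same strand. Pecam1 (2.21 against 0.157 CPM in the controls) and Chgb (2.07 against 0.157 CPM) rose below that cut, while Cdh5 (0.495 against 0.986 CPM) and Vwf (0.377 against 0.901 CPM) fell. Of the markers 28 stayed at 0 in all libraries, among them Ins1, Ins2, Gcg and Adgre1, which gives no sign of the cells those mark. The markers as a set do not decide whether RNA of other cell types contributed.

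The fall of long genes may reflect technical properties of the genes. The gap between the longest and the 4th decile of span, which had the lowest and highest medians and were picked for that, was −0.72 (log2, 95% bootstrap interval −0.76 to −0.65 over genes) and stayed at −0.53 (−0.59 to −0.47) after GC content, exonic length and expression were fitted, which argues against these as the whole cause. Early stopping of RNA polymerase II along long genes stays open, since counts summed over exons hold no position along the gene.

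The rise of mitochondrially encoded RNA (median log2 fold 1.13) may come from cytoplasm carried into the chromatin fraction. Cytosolic ribosomal protein genes, whose mRNA such carry-over would bring, had an upper quartile of 0.24, which argues against cytoplasm carried over with its mRNA as the whole cause. The lower count share of nuclear-retained long noncoding RNAs (3.48% against 5.05%) goes with a less pure fraction, although members moved apart, with Neat1 at log2 −0.97 and Kcnq1ot1 at 0.82, so a change in purity stays open. Nuclear-encoded respiratory chain and mitochondrial ribosomal protein genes also moved up, by less (medians 0.45 and 0.32). Mitochondria pelleted with chromatin, and a change in mitochondrial transcription, cannot be told apart here, because no value in these libraries says where the RNA lay.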
